A study of Mus musculus with 12 samples.

How the data were processed

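RNA-seq libraries were made from nucleus accumbens tissue of 12 male mice. RNA was purified from snap-frozen punches with the RNeasy kit, ribosomal RNA was removed with Illumina Ribo-Zero, and 1 library was sequenced per mouse, according to the sample descriptions. The samples fall into 3 groups of 4 by the construct that a herpes simplex virus (HSV) vector delivered by stereotaxic injection: ZFP189WT, ZFP189VPR or ZFP189NFD. All mice had received cocaine injections for 3 days. Groups and mouse numbers were taken from the sample titles.

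The authors deposited raw read counts per gene, 1 table per library, as whole numbers without normalization. Their processing notes name Trimmomatic 0.39 for read trimming, STAR 2.7.11a for alignment and GRCm39 as the genome build. The counting program, its settings and the strandedness of the libraries are not given in the sources used here; the layout of the tables, with exon coordinates, strand and exon length for each gene, is that of featureCounts. Each table held 49315 genes, of which 48970 had a symbol in the reference annotation. The gene coordinates were compared with a GRCm38 annotation (GENCODE M21): of the 49056 genes found in both, 44858 (91.4%) had the same start and end to the base, so all coordinates given here are GRCm38 coordinates as in the tables. The series title concerns transposable elements, but the tables held 0 entries for them, so transposable elements were not analysed here. Counts over genes with exons on both strands of the same stretch, or with close copies elsewhere, may include reads from the neighbour or the copy. Exon sharing was computed for every gene named and is given for those where it reached 8 percent.

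Total counts per library ran from 12093837 to 18957710, and 28265 to 29458 genes had at least 1 count. A count of 3, the limit that a count of 0 allows, corresponded to 0.158 to 0.248 CPM (counts scaled to a common library size) in single libraries. This floor covers counting error only, since reads without molecular identifiers are not independent molecules. The 4 mice of a group show the spread between animals, and SD values are given over them.

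Genes were tested in R 4.3.3 with edgeR 4.0.16. The function filterByExpr kept 21349 genes, libraries were scaled by the trimmed mean of M values (TMM; factors 0.944 to 1.075), and the quasi-likelihood F test was run in 1 model over all 12 libraries with a term for the construct and no covariate. The common biological coefficient of variation was 0.223. The 3 comparisons were VPR against NFD, WT against NFD and VPR against WT, each two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of F. Log2 CPM values, and the list medians computed from them, used a prior count of 2. The fold changes of single genes were fitted with the default prior count of edgeR instead. Near the floor they depend on that default, so for these genes the text gives CPM.

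A set of 47 gene lists covering cell types, immune and stress responses, synaptic function, chromatin and gene families was fixed before the data were examined, as were the model, the comparisons, the rule for named genes and the alternatives not called later additions here. Lists were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, and the p-values were adjusted over the 141 tests of 47 lists in 3 comparisons. Camera asks whether the genes of a list moved relative to the other genes. With so low a preset correlation its p-values understate the spread between mice where the genes of a list vary together. It was repeated with the correlation estimated from the data, and fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it. Members past 0.05 were counted over all genes tested and adjusted over the list alone. The mean log2 CPM of each list in each library was also compared between groups by an exact permutation test (two-sided), whose smallest possible p for 4 against 4 libraries is 0.0286. Correlations between list means were computed over the 12 libraries after the mean of each construct was subtracted, with exact permutation of the libraries within constructs.

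Named genes followed a fixed rule. Where fewer than 5 genes passed the threshold, the 5 genes with the smallest unadjusted p in each direction were named if they averaged at least 1 CPM over the 8 libraries compared and had a symbol that is not a predicted model or clone name. For a list called by camera with no member past the threshold, up to 3 members with the smallest p were allowed; 2 were named, a number set after their values had been seen. A further 10 genes were chosen for the system studied: Zfp189, Trim28, Setdb1, Drd1, Drd2, Tac1, Penk, Pdyn, Fos and Fosb. No named gene passed the edgeR threshold over all genes with all 12 libraries, so named genes are given as values. The values of a few genes that the rule names are not reported here.

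The alternatives tried were DESeq2 size factors in edgeR (RLE), the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter beyond 1 count, a filter of at least 1 CPM in at least 8 libraries, only the 2 groups compared in the model, the mouse number as a block, 17834 protein-coding and long non-coding genes only, a threshold of 0.1, leaving out each library in turn, and, for the lists, the estimated correlation and fry. Chosen after seeing the data were the model without the 4 libraries with the highest mean of glutamatergic neuron markers, that mean as a covariate, and 1 or 2 surrogate variables from sva 3.50.0. The 4 libraries were VPR replicates 1 and 2, WT replicate 4 and NFD replicate 3, so VPR replicates 3 and 4 alone stood for VPR. The first of 2 surrogate variables partly follows the construct, at -0.438 to -0.088 in VPR and -0.146 to 0.403 in NFD. The glutamatergic mean differs between these groups as well. Such covariates can take away an effect of VPR together with differences between mice. The correlation of fold changes between comparisons that share the NFD libraries was set beside simulated unchanged genes, 100 relabelled sets and 6 assignments of the NFD libraries to 1 comparison or the other. Each comparison was also recomputed over all 35 splits of its 8 libraries into 4 and 4.

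The procedure was tested on simulated data with independent genes, the same number of libraries, like dispersion and 20936 genes passing the filter. With 50 genes changed at each size in the comparison of VPR with NFD, edgeR recovered 18% of 1.5-fold, 52% of 2-fold, 90% of 4-fold and 96% of 8-fold changes, with 7 false calls. Where no gene was changed, edgeR made 0 calls and DESeq2 made 10. With changed genes, DESeq2 made 34 false calls among 182 in VPR against NFD. A shift put into the interferon list was called by camera (adjusted p = 3.69e-14 for VPR against NFD) with 0 other lists called. With independent genes, this does not show how often camera calls lists whose genes vary together. Nor do the recovery rates carry over to genes that vary strongly between mice. In the real data Irgm1, 14.5-fold lower with VPR than with NFD, had an edgeR adjusted p of 0.189. Figures were drawn with matplotlib 3.10.9, and tables were prepared in Python 3.11.15 with pandas 2.3.3.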

Results

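RNA-seq of the nucleus accumbens, a region of the ventral striatum made up mostly of GABAergic medium spiny neurons, was compared between 12 male mice. Each mouse carried 1 of 3 forms of ZFP189, a zinc finger transcription factor of the KRAB family, delivered locally by an HSV vector. ZFP189WT is the wild-type protein, ZFP189VPR carries the VPR fusion of transcriptional activation domains, and ZFP189NFD carries no functional domain and served as the control. Each group held 4 mice, 1 library per mouse, and all mice had received 3 days of cocaine, so the comparisons are between constructs and not between cocaine and saline. Total counts per library ran from 12093837 (NFD replicate 2) to 18957710 (VPR replicate 4). Between 28265 and 29458 genes were detected per library, and mitochondrially encoded transcripts held 1.9% to 2.49% of counts, with the lowest shares in VPR replicates 1 and 2 and WT replicate 4 (1.96%, 1.9% and 1.93%). The small nuclear RNA Rn7sk held 0.92% to 1.56% of counts with VPR, 1.36% in WT replicate 4, 1.67% to 1.95% in the other WT libraries and 1.61% to 2% with NFD. The composition of the libraries therefore differed along with the list means below, and the cause was not tested.

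The libraries varied in innate immune genes and in markers of glutamatergic neurons, within groups as well as between them. The mean log2 CPM of 53 genes of double-stranded RNA sensing and the interferon response was 4.96, 6.31, 3.16 and 5.26 in NFD replicates 1 to 4, 6.10, 4.73, 5.56 and 1.56 in WT, and 1.35, 1.59, 1.20 and 3.07 in VPR. WT replicate 4 lay within the range of the VPR libraries. The mean of 20 cortical and other glutamatergic neuron markers was 3.13, 1.48, 4.43 and 1.08 in NFD, 1.32, 3.21, 1.73 and 5.04 in WT, and 5.31, 5.62, 3.93 and 3.67 in VPR, so that WT replicate 4 and NFD replicate 3 stood with the VPR libraries. Over the 12 libraries, after the mean of each construct was subtracted, the glutamatergic mean fell as the interferon mean rose (Pearson r = -0.87, exact permutation p = 0.00311, adjusted p = 0.0142 over 46 lists correlated with the interferon list; Spearman rho = -0.86, exact permutation p = 0.00326, adjusted p = 0.0214). Without the 2 libraries farthest from the median of the interferon mean, r was -0.69. The first principal component of all genes tested held 56.6% of the variance.

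**Figure D1:**
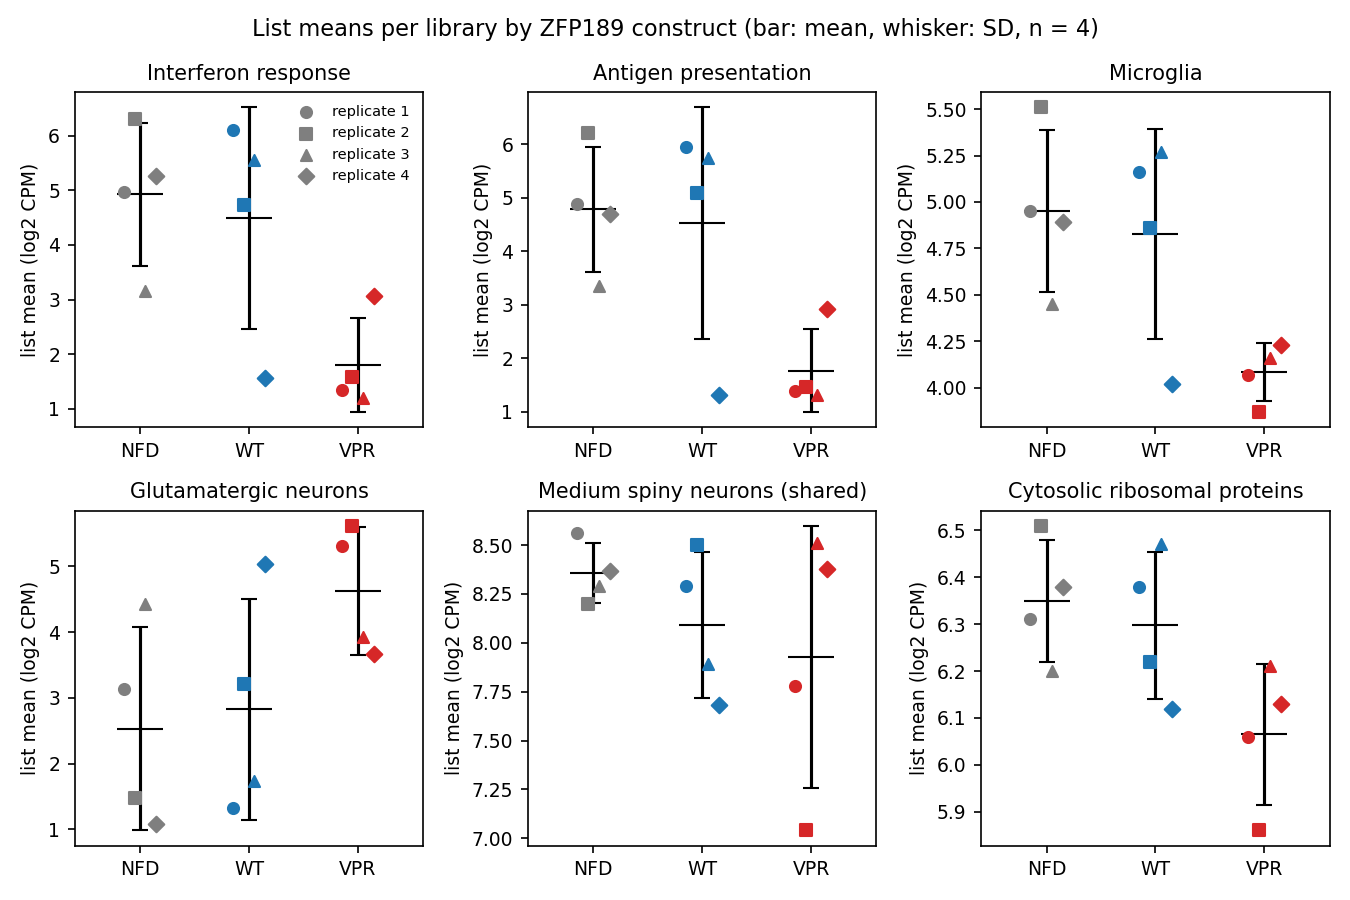
Mean log2 CPM of 6 gene lists (interferon response, antigen presentation, microglia, glutamatergic neurons, shared medium spiny neuron markers and cytosolic ribosomal proteins) in each of the 12 libraries, by construct, with bars for the group mean and SD (n = 4). The interferon list lies between 1.20 and 3.07 in the VPR libraries and between 3.16 and 6.31 in the NFD libraries, while WT replicate 4 (1.56) lies among the VPR libraries.

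**Figure D2:**
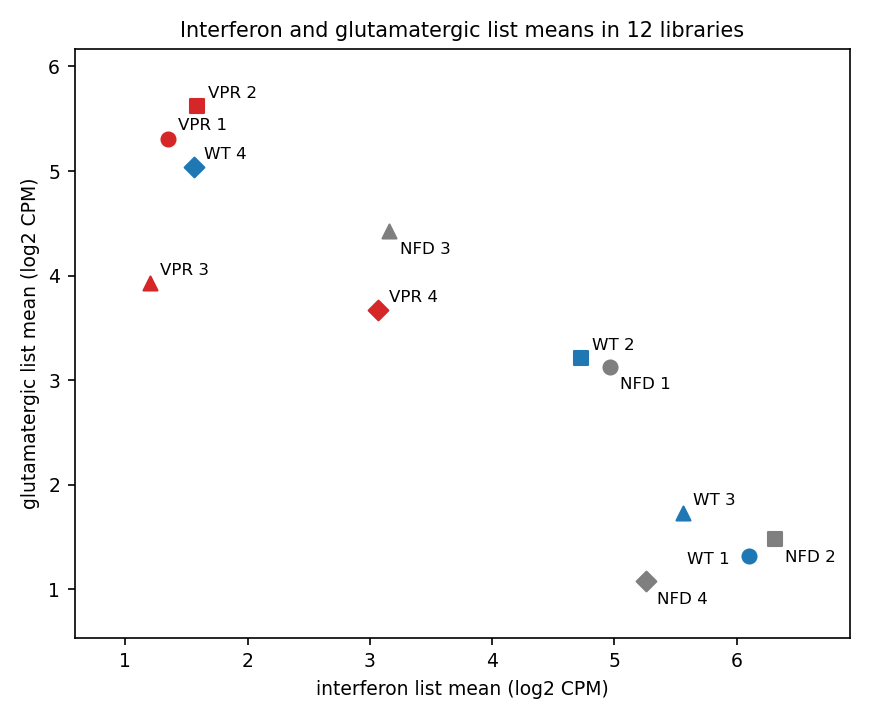
Mean log2 CPM of the interferon list against that of the glutamatergic list, 1 point per library, coloured by construct. VPR replicates 1 and 2 and WT replicate 4 combine glutamatergic means of 5.31, 5.62 and 5.04 with interferon means of 1.35, 1.59 and 1.56.

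VPR against NFD asks what an activator form of ZFP189 does relative to a form without a functional domain. Genes of the antiviral interferon response were lower with VPR by a median of 10.3-fold, and genes of antigen presentation by a median of 8.54-fold. With 1 library left out the interferon median ran from -4.19 (without NFD replicate 3) to -2.97 (without NFD replicate 2) on the log2 scale. The interferon list mean was 1.80 ± 0.86 with VPR and 4.92 ± 1.31 with NFD (log2 CPM, SD, n = 4 each), and all 4 VPR libraries lay below all 4 NFD libraries. Markers of microglia, leukocytes and reactive astrocytes were lower as well, and markers of glutamatergic neurons were higher by a median of 5.69-fold (log2 fold change 2.51; 3.15 without NFD replicate 3 and 1.95 without NFD replicate 2). No single gene passed the threshold in edgeR, so the calls are of whole lists. Camera called 17 of 47 lists, 5 higher and 12 lower, against 0 with an estimated correlation and 0 with fry. By exact permutation of the list means, p was 0.0286, the smallest possible, for the interferon, antigen presentation, leukocyte, microglia, endothelial and protocadherin gamma lists, and 0.0857 for the glutamatergic list. After adjustment over all lists and comparisons the smallest permutation p was 0.448.

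The interferon list fell (camera, median log2 fold change -3.36, adjusted p = 4.45e-24; adjusted p = 0.816 with an estimated correlation). In models chosen after seeing the data the median shrank to -1.33 with the glutamatergic mean as a covariate and to -0.55 and -0.56 with 1 and 2 surrogate variables, and the list was still called. Of its 53 tested genes 52 were lower, 51 passed when adjusted over the list alone, and 0 passed over all genes in edgeR, against 47 in DESeq2. Mx1, a GTPase that blocks viral replication, stood at 0.459 ± 0.425 CPM with VPR and 26.3 ± 24.5 CPM with NFD. Irgm1, an interferon-induced GTPase, stood at 7.31 ± 5.34 and 107 ± 86.7 CPM (log2 fold change -3.86, SE 0.92, edgeR adjusted p = 0.189). The antigen presentation list fell (median log2 fold change -3.09, adjusted p = 1.33e-11; 0.816 with an estimated correlation), with 19 of 20 genes past the threshold adjusted over the list alone. Its median was -1.16 with the covariate and -0.36 with 1 or 2 surrogate variables, still called. B2m, the light chain of MHC class I, was 34.6 ± 16.4 CPM with VPR and 252 ± 163 CPM with NFD, and the peptide transporter gene Tap1 was 3.56 ± 3.76 and 63.2 ± 53.6 CPM. All 4 VPR libraries lay below all 4 NFD libraries for each of these 4 genes.

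Markers of immune and glial cells fell in the same comparison. These lists are not independent readings. Within constructs their means rose with the interferon mean (Pearson r from 0.86 for cytokines and chemokines to 0.95 for reactive astrocytes). Cxcl10 is on both the cytokine and the reactive astrocyte list. The microglia list fell by a median of 1.84-fold (camera adjusted p = 1.19e-10; 0.816 with an estimated correlation), with 17 of 20 genes past the threshold adjusted over the list alone, and activated microglia and macrophages by 1.74-fold (adjusted p = 1.54e-06; 13 of 24). Infiltrating leukocytes fell by 3.37-fold (adjusted p = 3.38e-05; 10 of 17), cytokines and chemokines by 2.40-fold (adjusted p = 8.59e-07; 17 of 22), reactive astrocytes by 2.29-fold (adjusted p = 2.42e-06; 15 of 24) and endothelial cells and pericytes by 1.14-fold (adjusted p = 0.00273; 3 of 23). With an estimated correlation the adjusted p of each of these lists was 0.816. Without NFD replicate 2 the median log2 fold change shrank from -1.26 to -0.80 for cytokines and chemokines, from -1.20 to -0.71 for reactive astrocytes and from -0.80 to -0.52 for activated microglia and macrophages. In models chosen after seeing the data, all of these calls stayed without the 4 libraries highest in glutamatergic markers, but most were lost with covariates. The former setting leaves out NFD replicate 3, the NFD library lowest in the interferon mean. With the glutamatergic covariate only the microglia (-0.36) and cytokine (-0.35) lists were called. With 1 or 2 surrogate variables the microglia list (-0.13 with each) was called as lower. Activated microglia (0, turned, with each), cytokines (-0.08 with each), leukocytes (-0.04 and -0.02) and endothelial cells (-0.03 with each) were not called. Reactive astrocytes turned to 0.24 with 1 surrogate variable, not called, and were called as higher with 2 (0.24). Trem2, a microglial lipid receptor, was 7.36 ± 1.22 CPM with VPR and 15.2 ± 4.88 CPM with NFD. Tspo was 0.847 ± 0.337 and 5.33 ± 3.59 CPM, the Fc receptor gene Fcgr3 9.62 ± 1.40 and 22.7 ± 6.99 CPM, Cd52 0.891 ± 0.385 and 8.54 ± 7.18 CPM, and Plac8 0.168 ± 0.139 and 8.25 ± 8.87 CPM. The cytokine genes Il1a and Ccl12 were 0.398 ± 0.192 and 0.459 ± 0.342 CPM with VPR, against 1.36 ± 0.398 and 8.10 ± 5.32 CPM. The complement gene C4b was 50.2 ± 34.1 and 269 ± 141 CPM, the chemokine gene Cxcl10 2.14 ± 2.5 and 61.3 ± 78.9 CPM, and the endothelial genes Ly6a and Cdh5 6.03 ± 2.23 and 7.82 ± 0.904 CPM with VPR, against 28.7 ± 19.9 and 11.6 ± 1.28 CPM. General astrocyte markers were not called (median log2 fold change -0.06, adjusted p = 0.685), nor were oligodendrocytes (0.12, adjusted p = 0.0768).

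Neuronal genes split by type. The glutamatergic list rose (median log2 fold change 2.51, camera adjusted p = 3.03e-06; 0.816 with an estimated correlation). Of its 20 genes 19 were higher and 0 passed adjusted over the list alone, and its mean was 4.63 ± 0.98 with VPR and 2.53 ± 1.55 with NFD. Rspo2, a secreted activator of Wnt signalling, was 4.64 ± 4 and 0.601 ± 0.516 CPM, and the forebrain transcription factor gene Emx2 was 19.7 ± 2.37 and 12.1 ± 1.23 CPM. All 4 VPR libraries lay above all 4 NFD libraries for both genes. Presynaptic release genes rose (median 0.34, adjusted p = 0.000185; 0.816 with an estimated correlation), but were called as lower with 1 or 2 surrogate variables (-0.11 with each), alternatives chosen after seeing the data. Rims1 was 389 ± 130 and 230 ± 62.1 CPM and Nrxn2 511 ± 132 and 351 ± 67.2 CPM. Potassium and sodium channels, not all of them voltage-gated, rose (0.28, adjusted p = 0.011; 0.816 with an estimated correlation), with Kcnj9 at 91.5 ± 42.4 and 47.3 ± 17 CPM and Kcnb2 at 42.5 ± 6.34 and 34.3 ± 3.05 CPM. They were not called without NFD replicate 2 (0.21) or VPR replicate 2 (0.18). Immediate early genes rose (0.21, adjusted p = 0.0332; 0.831 with an estimated correlation). They were not called without NFD replicate 1 (0.21), NFD replicate 4 (0.11), VPR replicate 1 (0.14) or VPR replicate 2 (0.16). Their members Vgf and Bdnf, both secreted in an activity-dependent way, were 381 ± 54.2 and 14.7 ± 13.5 CPM with VPR and 300 ± 13.1 and 2.88 ± 3.66 CPM with NFD. Bdnf is on the glutamatergic list too, and was highest in the libraries highest in that list's mean. These were VPR replicates 1 and 2 (23.4 and 28.9 CPM), WT replicate 4 (12.7) and NFD replicate 3 (8.29). Cholesterol synthesis genes rose (0.33, adjusted p = 4.63e-06; 0.816 with an estimated correlation), with Cyp51 at 53.9 ± 9.39 and 40.2 ± 2.94 CPM and Insig1 at 53.8 ± 15.7 and 35.1 ± 9.40 CPM. With 1 or 2 surrogate variables the medians turned for the glutamatergic (-0.36 and -0.34), channel (-0.09 with each), immediate early (-0.09 and -0.08) and cholesterol lists (-0.04 with each), none of them called.

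Shared medium spiny neuron markers fell in VPR against NFD (median log2 fold change -0.44, camera adjusted p = 0.000648; 0.816 with an estimated correlation). Gnal, the G protein subunit of striatal dopamine signalling, was 547 ± 167 CPM with VPR and 737 ± 81.3 CPM with NFD. The cannabinoid receptor gene Cnr1, on the same list, was 150 ± 72.7 and 78.8 ± 28.7 CPM. D1 medium spiny neuron markers fell (-0.45, adjusted p = 0.0231; 0.816 with an estimated correlation), with Crym at 103 ± 57.3 and 196 ± 50.9 CPM. Without VPR replicate 2 the medians were -0.13 for shared and -0.26 for D1 medium spiny neuron markers, and neither was called, nor were the D1 markers without NFD replicate 3 (-0.53). With the glutamatergic mean as a covariate, an alternative chosen after seeing the data, the presynaptic, channel, immediate early, cholesterol and both medium spiny neuron lists were not called. Without the 4 libraries highest in glutamatergic markers, a later choice too, the shared medium spiny neuron median turned to 0.02, and neither this list nor the D1 (-0.15) and immediate early lists (-0.02) were called. Neither medium spiny neuron list was called with 1 or 2 surrogate variables. The glutamatergic list cannot be judged in that model, which removes its own mean.

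Cytosolic ribosomal protein genes fell (median log2 fold change -0.31, camera adjusted p = 6.98e-16; 0.816 with an estimated correlation), with 47 of 79 genes lower and 1 higher past the threshold adjusted over the list alone. Rps28 was 32.8 ± 6.77 CPM with VPR and 52 ± 4.34 CPM with NFD, and Rpl37 42.8 ± 7.64 and 69.2 ± 6.57 CPM. The median was -0.11 with the glutamatergic covariate and -0.06 with 1 or 2 surrogate variables, models chosen after seeing the data, and was still called. The protocadherin gamma cluster, which encodes neuronal adhesion proteins from 1 array on chromosome 18, fell (-0.35, adjusted p = 4.80e-06; 0.816 with an estimated correlation), with 0 of 22 genes past the threshold adjusted over the list alone. Pcdhga2 was 10.1 ± 1.62 and 14.5 ± 1.85 CPM and Pcdhga7 16.1 ± 3.29 and 22 ± 1.71 CPM. The protocadherin median was -0.22 without VPR replicate 2, -0.16 with the covariate and -0.11 with 1 or 2 surrogate variables, not called with the latter. Members of the array share exons (45.1% of the exon bases of Pcdhga2 and 40.6% of those of Pcdhga7), so their counts are not independent.

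Over single genes, 0 of 21349 passed in edgeR, and the smallest adjusted p was 0.189. An unadjusted p under 0.05 was found for 3878 genes (18.2%), where 1067 are expected by chance. DESeq2 called 587 genes in this comparison, 154 higher and 433 lower, of which 47 were in the interferon list and 18 in the antigen presentation list. Among the 5 higher genes with the smallest p were the mitochondrial tRNA gene mt-Te (chromosome MT, 14071 to 14139; 33.0 ± 7.96 and 18.1 ± 3.19 CPM) and the transcriptional repressor gene Dr1 (chromosome 5, 108268897 to 108280526; 25.1 ± 3.44 and 18.3 ± 0.943 CPM). The others were Utp14b (146 ± 18.3 and 103 ± 5.53 CPM) and the splicing factor genes Zrsr2 (58.3 ± 3.38 and 46.6 ± 2.49 CPM) and Pnn (166 ± 13.4 and 129 ± 5.96 CPM). The 5 lower genes included Ano5 (2.13 ± 0.331 and 4.54 ± 0.862 CPM), Lactb (12.1 ± 1.76 and 17.6 ± 1.26 CPM) and the immune checkpoint gene Lag3 (chromosome 6, 124904361 to 124911705; 5.56 ± 0.972 and 13.2 ± 2.98 CPM). The imprinted gene Mest (chromosome 6, 30723547 to 30748465; 56.7 ± 5.81 and 74.9 ± 5.70 CPM) and the melanocortin receptor gene Mc4r (chromosome 18, 66857715 to 66860472; 0.758 ± 0.25 and 1.94 ± 0.656 CPM) completed them. Each of these 10 genes had an edgeR adjusted p of 0.189.

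Zfp189 itself (ENSMUSG00000039634, chromosome 4, 49521176 to 49531517) was 18 ± 3.07 CPM with VPR, 20.9 ± 5.97 CPM with NFD and 22.1 ± 3.95 CPM with WT (SD, n = 4 each). Its log2 fold change was -0.21 (SE 0.19, edgeR adjusted p = 0.556) for VPR against NFD, 0.08 (adjusted p = 1) for WT against NFD and -0.30 (adjusted p = 0.497) for VPR against WT. All 3 constructs are named for ZFP189, so this gene's counts separate the groups only as far as the constructs carry the counted exons and differ in them. Without NFD replicate 2 the difference between VPR and NFD was 0, and that between WT and NFD was -0.02 without NFD replicate 3 and -0.01 without WT replicate 1.

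The co-repressor genes Trim28 and Setdb1 were 71.4 ± 5.17 and 61.1 ± 3.60 CPM with VPR, 78.1 ± 2.24 and 66.0 ± 4.66 CPM with NFD, and 76.5 ± 3.74 and 68.7 ± 2.63 CPM with WT. The dopamine receptor genes Drd1 and Drd2 were 128 ± 69.9 and 106 ± 67.4 CPM with VPR, 198 ± 22.9 and 146 ± 16.2 CPM with NFD, and 157 ± 48.7 and 121 ± 43.9 CPM with WT. The neuropeptide genes Tac1, Penk and Pdyn were 83.5 ± 44.2, 444 ± 280 and 105 ± 66.8 CPM with VPR, 119 ± 17.8, 805 ± 114 and 186 ± 28.9 CPM with NFD, and 102 ± 34.1, 615 ± 230 and 158 ± 63.9 CPM with WT. Fos and Fosb, induced by neuronal activity, were 42.5 ± 15.4 and 43.4 ± 8.24 CPM with VPR, 41.0 ± 27.6 and 53.4 ± 39.2 CPM with NFD, and 33.7 ± 6.64 and 36.2 ± 12 CPM with WT. Neither Zfp189 nor any of these 9 genes passed the edgeR threshold in any of the 3 comparisons. The direction for Fos turned without NFD replicate 1, 3 or 4 or VPR replicate 1 or 2 (VPR against NFD, -0.18 to 0.63 over the libraries left out), and that for Fosb without NFD replicate 2 (-0.51 to 0.36).

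**Figure D3:**
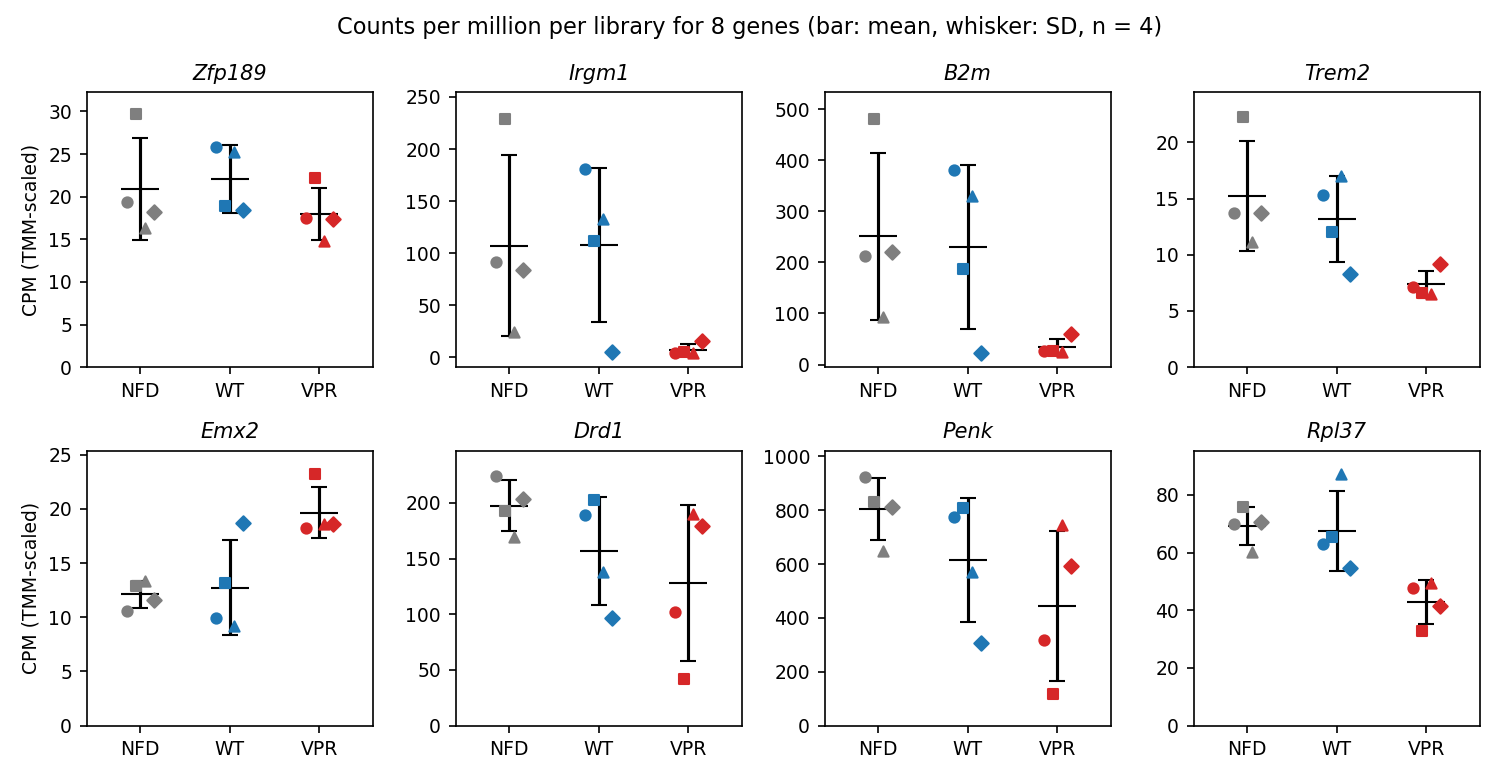
CPM of Zfp189, Irgm1, B2m, Trem2, Emx2, Drd1, Penk and Rpl37 in each of the 12 libraries, with the group mean and SD (n = 4). Irgm1 lies at 4.22 to 15.3 CPM in the VPR libraries and at 24.3 to 229 CPM in the NFD libraries, WT replicate 4 (5.45 CPM) lies with VPR, and Zfp189 overlaps between the 3 groups.

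WT against NFD asks what the wild-type protein does relative to the form without a functional domain. The differences were small next to the spread between mice. The interferon list mean was 4.49 ± 2.03 with WT and 4.92 ± 1.31 with NFD, and the glutamatergic mean was 2.82 ± 1.69 and 2.53 ± 1.55 (not called, adjusted p = 0.513). Camera called 6 of 47 lists, all lower, against 0 with an estimated correlation and 0 with fry, and 0 members of any passed the threshold adjusted over the list alone. At least as many lists were called in 34 of 35 splits of these libraries, the real grouping included. The falls given next are therefore values, not effects of the wild-type protein shown beyond the spread between mice.

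Shared medium spiny neuron markers fell (median log2 fold change -0.26, camera adjusted p = 8.39e-06; 0.816 with an estimated correlation; 26 of 27 genes lower). The phosphoprotein gene Arpp19 was 138 ± 13.1 CPM with WT and 164 ± 11.6 CPM with NFD, and Rgs14, a regulator of G protein signalling, 57.8 ± 13.1 and 70.3 ± 5.77 CPM. The protocadherin gamma cluster fell (-0.14, adjusted p = 6.29e-06; 0.816 with an estimated correlation; 22 of 22 lower), with Pcdhga8, 47.1% of its exon bases shared, at 18.3 ± 2.71 and 23.1 ± 1.63 CPM and Pcdhga2 at 11.9 ± 1.53 and 14.5 ± 1.85 CPM. Nuclear genes of oxidative phosphorylation fell (-0.06, adjusted p = 0.00425; 0.816 with an estimated correlation), with the complex I genes Ndufs7 at 27 ± 3.02 and 31.6 ± 2.04 CPM and Ndufs3 at 38.3 ± 1.07 and 41.5 ± 1.92 CPM. Immediate early genes fell (-0.14, adjusted p = 0.0174; 0.816 with an estimated correlation), with Egr3 at 51.9 ± 9.48 and 63.7 ± 13.2 CPM and Inhba at 21.7 ± 3.17 and 24.9 ± 3.52 CPM. Cytosolic ribosomal protein genes fell (-0.05, adjusted p = 0.0153; 0.855 with an estimated correlation), with Rpl38 at 112 ± 8.87 and 124 ± 5.32 CPM and Rpl3l at 0.314 ± 0.222 and 0.697 ± 0.257 CPM. The interferon list fell (-0.45, adjusted p = 0.0174; 0.855 with an estimated correlation), with Ifi27 at 29.2 ± 11.5 and 39.4 ± 6.68 CPM and Mavs, which went the other way, at 8.32 ± 0.836 and 7.49 ± 0.802 CPM.

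Single libraries decided several of these calls. Without WT replicate 4 the interferon list was called in the other direction, as higher with WT (median 0.44, adjusted p = 1.49e-05, against 2.24e-09 to 0.878 over the alternatives for this list). Its median was 0.02 without NFD replicate 2, -1.06 without NFD replicate 3, -0.91 without WT replicate 1 and -0.76 without WT replicate 3. The ribosomal median was 0.02 without WT replicate 4 and 0 without NFD replicate 2, not called. Neither list was called without NFD replicate 4 (-0.31 and -0.04). Immediate early genes were not called without NFD replicate 2 (-0.03), NFD replicate 3 (-0.16), WT replicate 1 (-0.11) or WT replicate 3 (0). The shared medium spiny neuron median was -0.12 without WT replicate 4, still called. In the models chosen after seeing the data the ribosomal list was not called, and the interferon list was called only with 1 or 2 surrogate variables (-0.18 and -0.26). Oxidative phosphorylation was not called without NFD replicate 1 (-0.04), NFD replicate 3 (-0.02), WT replicate 1 (-0.03) or WT replicate 3 (-0.04), and the ribosomal list not without WT replicate 2 (-0.03). The 6 lists became 15 (9 higher, 6 lower) without NFD replicate 2, 12 (2 higher, 10 lower) without NFD replicate 3 and 10 (3 higher, 7 lower) without WT replicate 1. They became 11 (2 higher, 9 lower) without WT replicate 2 and 17 (9 higher, 8 lower) without WT replicate 4. By exact permutation of the list means the smallest p was 0.114.

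Over single genes, 0 of 21349 passed in edgeR in WT against NFD, and DESeq2 called 0. An unadjusted p under 0.05 was found for 362 genes (1.7%), against 1067 expected by chance, and the smallest adjusted p was 1. The higher genes with the smallest p were Stac (chromosome 9, 111561437 to 111690348; 3.08 ± 0.893 CPM with WT and 1.64 ± 0.409 CPM with NFD), Prss52 (1.73 ± 0.208 and 0.852 ± 0.359 CPM) and Rhebl1 (3.41 ± 1.18 and 2.01 ± 0.324 CPM). The adhesion gene Jam3 (20.5 ± 1.44 and 17.4 ± 0.821 CPM) and the sialyltransferase gene St6galnac2 (2.18 ± 0.562 and 1.32 ± 0.231 CPM) came next. The lower genes were Cstf1 (chromosome 2, 172370681 to 172382448; 14.4 ± 0.951 and 19.3 ± 1.05 CPM), which encodes a subunit of the cleavage stimulation factor, and Triqk (6.87 ± 0.403 and 8.77 ± 0.821 CPM). Naaladl1 (0.903 ± 0.322 and 1.64 ± 0.396 CPM), the complex I gene Ndufb4 (29.6 ± 1.74 and 35 ± 2.35 CPM) and Adprm (9.13 ± 0.282 and 11 ± 0.623 CPM) were the others.

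VPR against WT compares the activator form directly with the wild-type protein. Interferon genes were lower with VPR by a median of 7.28-fold and antigen presentation genes by 7.57-fold. On the log2 scale the interferon median was -3.96 without WT replicate 4 and -2.26 without WT replicate 1, and the antigen presentation median -4.21 without WT replicate 4. Microglia, leukocyte and reactive astrocyte markers were lower too, and glutamatergic markers were higher by 3.72-fold (log2 fold change 1.90; 2.75 without WT replicate 4 and 1.38 without WT replicate 1). In each of these lists WT replicate 4 lay within the range of the VPR libraries, and the interferon list mean of WT was 4.49 ± 2.03 against 1.80 ± 0.86 with VPR. Camera called 21 of 47 lists, 8 higher and 13 lower, against 0 with an estimated correlation and 0 with fry. By exact permutation of the list means the smallest p was 0.0571.

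Lower with VPR than with WT were the interferon list (median log2 fold change -2.86, camera adjusted p = 3.96e-23; 0.816 with an estimated correlation; 51 of 53 genes past the threshold adjusted over the list alone) and antigen presentation (-2.92, adjusted p = 4.79e-12; 0.816 with an estimated correlation; 19 of 20). The interferon median shrank to -1.05 with the glutamatergic mean as a covariate and to -0.31 and -0.19 with 1 and 2 surrogate variables, models chosen after seeing the data, and was still called. Mx1 and Irgm1 were 26.6 ± 24.7 and 108 ± 74.2 CPM with WT. The MHC class II genes H2-Eb1 and Cd74 were 0.436 ± 0.307 and 2.08 ± 0.65 CPM with VPR and 12.4 ± 9.28 and 35.7 ± 26.9 CPM with WT. Microglia fell by 1.64-fold (adjusted p = 3.87e-09; 0.816 with an estimated correlation; 16 of 20) and activated microglia and macrophages by 1.71-fold (adjusted p = 1.09e-07; 0.816 with an estimated correlation; 11 of 24). P2ry13, a microglial purine receptor, was 6.84 ± 1.10 and 11 ± 2.16 CPM, the protease gene Ctss 36.7 ± 12.1 and 130 ± 77.1 CPM, and the Fc receptor gene Fcgr2b 2.99 ± 0.666 and 13.3 ± 8.52 CPM. Tspo was 5.51 ± 3.17 CPM with WT. Infiltrating leukocytes fell by 3.76-fold (adjusted p = 1.13e-06; 0.816 with an estimated correlation; 11 of 17), with Cd52 and Plac8 at 9.03 ± 6.53 and 8.86 ± 8.02 CPM with WT. Cytokines and chemokines fell by 2.46-fold (adjusted p = 3.87e-09; 0.816 with an estimated correlation; 14 of 22). The chemokine gene Cxcl9 had 0 counts in WT replicate 4 and in VPR replicates 1 and 2, and averaged 6.34 ± 4.89 CPM with WT and 0.0307 ± 0.0362 CPM, under the floor, with VPR. Il1a was 1.15 ± 0.0969 CPM with WT. Reactive astrocytes fell by 2.63-fold (adjusted p = 3.99e-08; 0.816 with an estimated correlation; 16 of 24), with the protease inhibitor gene Serpina3n at 6.87 ± 0.549 and 110 ± 83 CPM and the immunoproteasome gene Psmb8 at 1.77 ± 1.68 and 21.8 ± 15.4 CPM. Psmb8 is also on the antigen presentation list. The reactive astrocyte median was -0.86 without WT replicate 3. Endothelial cells and pericytes fell by 1.13-fold (adjusted p = 0.0171; 0.816 with an estimated correlation; 0 of 23). The tight junction gene Cldn5 was 5.05 ± 0.909 and 7.40 ± 1.26 CPM, and Ly6a 26.4 ± 16 CPM with WT. The endothelial list was not called without WT replicate 2 (-0.16) or WT replicate 3 (-0.09), nor with the covariate (-0.02). With 1 or 2 surrogate variables only the interferon and antigen presentation lists (-0.33 and -0.29) of these 8 were called. Turned, but not called, were the endothelial list with 1 and 2 (0.03 and 0) and activated microglia (0.04) and reactive astrocytes (0.08) with 2.

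Higher with VPR than with WT was the glutamatergic list (median log2 fold change 1.90, camera adjusted p = 3.03e-06; 0.816 with an estimated correlation), with the transcriptional regulator gene Lmo3 at 220 ± 89.7 CPM with VPR and 141 ± 41.7 CPM with WT, and Emx2 at 12.8 ± 4.36 CPM with WT. Immediate early genes rose (0.35, adjusted p = 3.63e-05; 0.816 with an estimated correlation), with Vgf at 293 ± 49.1 CPM with WT and Inhba at 27.3 ± 1.93 CPM with VPR. Presynaptic release genes rose (0.37, adjusted p = 9.70e-06; 0.816 with an estimated correlation), with Cplx2 at 1900 ± 172 and 1450 ± 218 CPM and Unc13a at 564 ± 90.6 and 447 ± 59.1 CPM. Potassium and sodium channels rose (0.32, adjusted p = 0.000114; 0.816 with an estimated correlation), with Kcnn2 at 32.5 ± 5.86 and 24 ± 5.06 CPM. Cholesterol synthesis genes rose (0.31, adjusted p = 5.11e-06; 0.816 with an estimated correlation), with Msmo1 at 37.9 ± 7.19 and 28.5 ± 5.29 CPM and Mvk at 9.88 ± 2.13 and 7.82 ± 0.815 CPM. Cocaine-linked synaptic plasticity genes rose (0.18, adjusted p = 0.0032; 0.816 with an estimated correlation). The transcription factor gene Creb1 was 75.3 ± 3.37 and 66.4 ± 4.32 CPM and the scaffold gene Homer1 264 ± 32.4 and 217 ± 35.9 CPM. Heat shock and unfolded protein response genes rose (0.12, adjusted p = 0.00399; 0.816 with an estimated correlation), with the chaperone genes Dnaja1 at 206 ± 14.6 and 171 ± 19.5 CPM and Calr at 528 ± 37.7 and 440 ± 35.5 CPM. Nuclear oxidative phosphorylation genes rose (0.07, adjusted p = 0.00236; 0.816 with an estimated correlation), with Ndufb10 at 116 ± 5.97 and 95.1 ± 8.57 CPM and Cox6c at 174 ± 15.9 and 139 ± 8.61 CPM. Of their members 0 passed adjusted over the list alone. The heat shock list was not called without VPR replicate 1 (0.05). With the glutamatergic mean as a covariate, an alternative chosen after seeing the data, only the heat shock list was still called among the 7 other than the glutamatergic list, which cannot be judged there. With 1 or 2 surrogate variables the medians turned for the glutamatergic (-0.43 and -0.38), presynaptic (-0.07 and -0.06), channel (-0.01 and -0.02), cholesterol (-0.04 and -0.01), oxidative phosphorylation (-0.04 with each) and cocaine-linked plasticity lists (0 and -0.03), none of them called. Immediate early genes (0.10 and 0.16) were not called either, and heat shock genes only with 2 surrogate variables (0.08). Without the 4 libraries highest in glutamatergic markers the immediate early (0.24), heat shock (0.03) and oxidative phosphorylation lists (0.04) were not called. Without VPR replicate 2 the presynaptic and channel medians were 0.24 and 0.21, and the immediate early median was 0.23 without WT replicate 3.

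Cytosolic ribosomal protein genes fell with VPR against WT (median log2 fold change -0.25, camera adjusted p = 1.66e-13; 0.816 with an estimated correlation), with 24 of 79 lower and 1 higher past the threshold adjusted over the list alone. Rpl37 was 67.5 ± 14 CPM with WT. Small nucleolar RNAs fell by a median of 1.18-fold (adjusted p = 0.00272; 0.816 with an estimated correlation), with Snora23 at 1.36 ± 0.52 and 2.48 ± 0.889 CPM and Snora30 at 1.95 ± 0.576 and 2.97 ± 0.55 CPM. Cell cycle genes fell (-0.45, adjusted p = 0.00629; 0.816 with an estimated correlation), with Ube2c at 1.13 ± 0.333 and 2.43 ± 1.12 CPM and Kif20a at 4.29 ± 1.02 and 6.31 ± 1.23 CPM. With 1 surrogate variable the cell cycle median turned to 0.13, not called, and with 2 the list was called as higher (0.26), models chosen after seeing the data. The protocadherin gamma cluster fell (-0.16, adjusted p = 0.0352; 0.816 with an estimated correlation), with Pcdhgb2, 43.4% of its exon bases shared, at 16.3 ± 2.66 and 20.9 ± 2.57 CPM and Pcdhga7 at 20.4 ± 2.97 CPM with WT. Imprinted genes fell (-0.17, adjusted p = 0.0486; 0.816 with an estimated correlation), with Mest at 76.2 ± 3.41 CPM with WT and the non-coding RNA gene H19 at 0.244 ± 0.215 and 3.45 ± 2.89 CPM. In the models chosen after seeing the data the ribosomal list was called with the covariate (-0.09) but not with 1 or 2 surrogate variables (-0.04 and -0.05). The small nucleolar RNA, protocadherin and imprinted lists were called in none of them, with the protocadherin median turned to 0.03 with 1 surrogate variable. The cell cycle list was not called with the covariate (-0.1). Small nucleolar RNAs were not called without VPR replicate 2 (-0.16), nor cell cycle genes without VPR replicate 3 (-0.42). The protocadherins were not called without VPR replicate 2 (-0.02), WT replicate 1 (-0.12) or WT replicate 2 (-0.16). Imprinted genes were not called without NFD replicate 1 or 4 (both -0.17), VPR replicate 1 (-0.13) or 2 (-0.08), or WT replicate 3 (-0.12) or 4 (-0.23). Nor were imprinted genes called with the mouse number as a block.

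Over single genes, 0 of 21349 passed in edgeR in VPR against WT, and the smallest adjusted p was 0.266. An unadjusted p under 0.05 was found for 2874 genes (13.5%). DESeq2 called 343 genes (41 higher, 302 lower), and edgeR called 581 (133 higher, 448 lower) once WT replicate 4 was left out, of which 286 were among the DESeq2 calls. WT replicate 4 is the WT library at the interferon level of the VPR libraries (1.56), so leaving it out widens the gap. Both sets of calls rest on largely the same libraries, so their overlap is no independent check. The 581 included 42 of the interferon list, 19 of antigen presentation and 12 of the microglia list. The higher genes with the smallest p over all 12 libraries were the Wnt regulator gene Nkd1 (chromosome 8, 88521354 to 88594884; 13.1 ± 1.14 CPM with VPR and 9.33 ± 0.187 CPM with WT) and Tmem101 (15.8 ± 0.999 and 12.2 ± 0.359 CPM). Next came Syne3 (5.56 ± 0.765 and 3.54 ± 0.208 CPM), the complex I gene mt-Nd3 (chromosome MT, 9459 to 9806; 22.7 ± 3.52 and 15.5 ± 1.44 CPM) and Dr1 (18.7 ± 0.14 CPM with WT). The lower genes were Mc4r (2.17 ± 0.222 CPM with WT), Magee2 (3.76 ± 0.498 and 7.11 ± 1.28 CPM), Mest, Dnah17 (7.38 ± 0.4 and 10.6 ± 0.749 CPM) and the fatty acid translocase gene Cd36 (0.321 ± 0.129 and 2.08 ± 1.15 CPM).

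**Figure D4:**
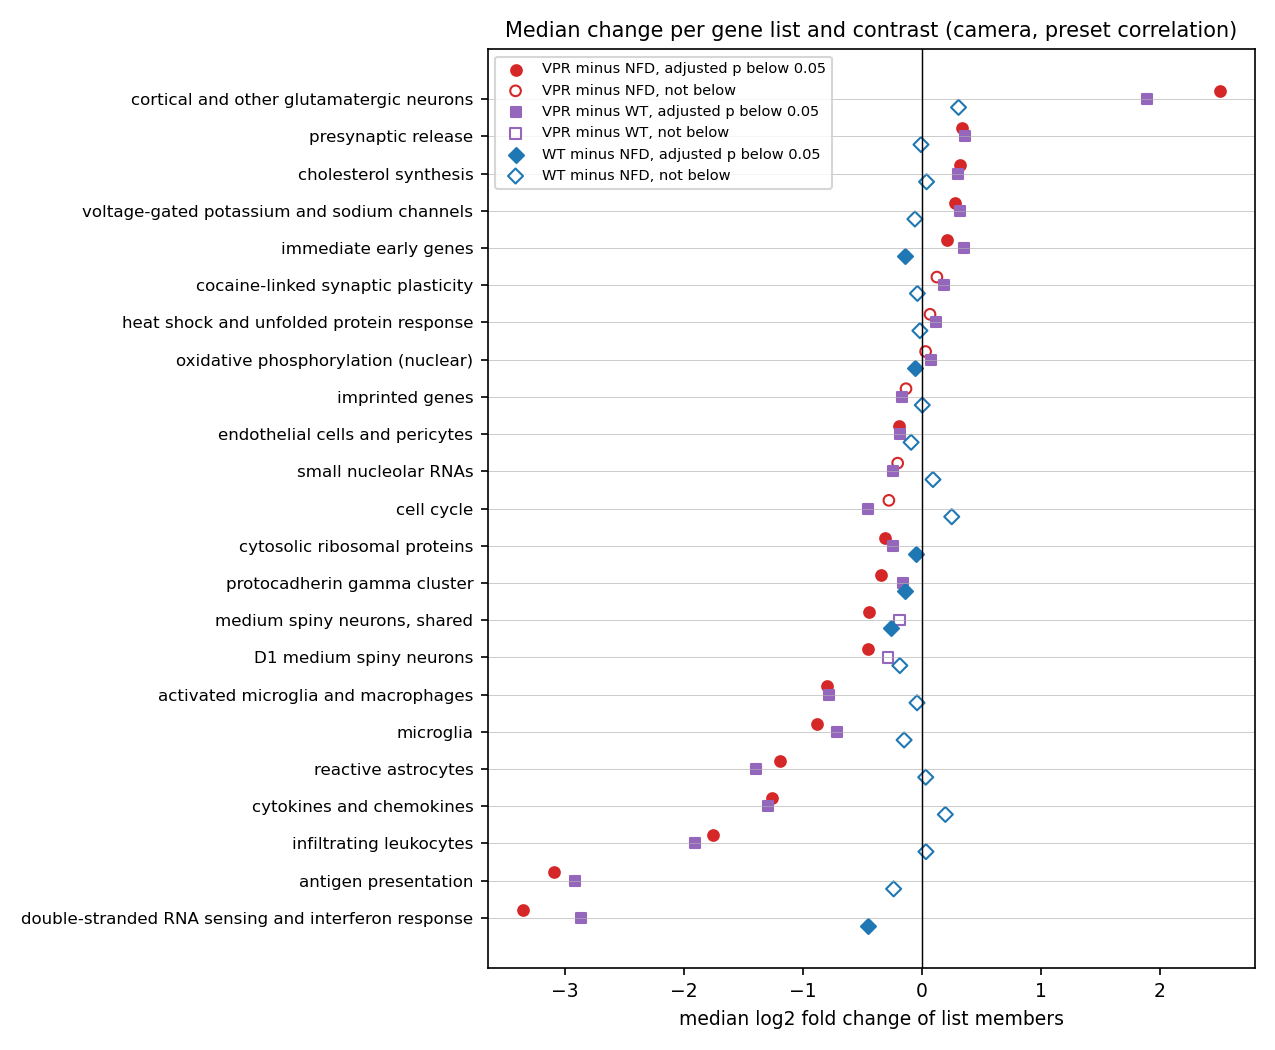
Median log2 fold change of the tested members of each list called by camera in at least 1 comparison, for VPR against NFD, WT against NFD and VPR against WT, with called lists marked as in the legend. The interferon list stands at -3.36 for VPR against NFD and at -0.45 for WT against NFD, and the glutamatergic list at 2.51 and 0.31.

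Lists not called in a comparison numbered 30 for VPR against NFD, 41 for WT against NFD and 26 for VPR against WT. KRAB co-repressors and heterochromatin genes, partners of KRAB zinc finger proteins, had medians of 0.04, 0.03 and -0.01 in these 3 comparisons, domesticated retroelement genes -0.01, -0.04 and -0.05, and the 368 Zfp genes -0.05, 0.01 and -0.04. D2 medium spiny neuron markers had medians of -0.28, -0.13 and -0.35, and GABA signalling genes -0.08, -0.06 and -0.12. The median and the mean log2 fold change differed in sign for lateral septum, olfactory and basal forebrain markers (0.10 and -0.15) and olfactory receptors in VPR against NFD, for astrocytes, activated microglia, extracellular matrix, replication histones, olfactory receptors and sex-linked genes in WT against NFD, and for the protocadherin beta cluster and olfactory receptors in VPR against WT, none of them called. For germline genes in VPR against NFD and KRAB co-repressors in VPR against WT the test pointed up while median and mean were below 0.

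Exons of some named genes are shared with other genes, and whether reads of the other gene were counted depends on the strandedness. On the opposite strand the shared part was 36.2% of the exon bases of Jam3, 33.2% of Kif20a, 23.1% of Mest, 22.8% of Ube2c, 14.5% of Cd52, 14.4% of Bdnf, 14.3% of Penk, 11.3% of Stac, 11.2% of Il1a, 10.3% of Pcdhga7, 9.9% of Dnaja1 and 8.8% of Emx2 and Pcdhga8. On the same strand the St6galnac2 entry named here shared 22.8% with a second entry of the same symbol.

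The comparisons of VPR and of WT with NFD use the same 4 NFD libraries, so their fold changes share chance values. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was 0.396, against a mean of 0.502 (range 0.485 to 0.518) for simulated genes without any change. With the NFD libraries divided between the comparisons the median correlation was 0.139 (range -0.439 to 0.489), and with relabelled libraries it was 0.462 (95% range -0.298 to 0.911).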

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

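Chosen after the result was seen were the tests of cortical tissue, of Zfp189 against genes of like abundance, of the punch placement and of an effect of VPR, and the splits of the samples for genes called by edgeR; the other tests were set before.

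Single libraries stood far from the other 3 of their group in 29 of 408 groups of values (7.1%), 26 of them above the others and 3 below. The rule flags about 5% of independent normal values. CPM values need not be normal and many of these genes vary together, so 5% is not the chance rate here. VPR replicate 4 held 8 of the 29, all in immune genes and all above the other VPR libraries, and these are not separate readings. Its antigen presentation list mean was 2.92 against 1.3 to 1.45. Irgm1 stood at 15.3 CPM (others 4.22 to 5.36), B2m at 59.2 (25.5 to 27.1), Tap1 at 9.15 (1.13 to 2.26) and Psmb8 at 4.29 (0.776 to 1.1). Ifi27 stood at 30.9 CPM (9.85 to 12.3), Ctss at 54.8 (29.1 to 31.5) and Fcgr2b at 3.98 (2.53 to 2.76).

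WT replicate 4 stood apart in Fcgr3, low at 9.27 CPM (others 24.3 to 27.4), and Cldn5, low at 5.51 (8 to 8.06). It was high in Rspo2 at 5.95 CPM (0.233 to 0.872) and Kcnj9 at 101 (37.3 to 47.3). NFD replicate 3 was high in Rspo2 at 1.37 CPM (0.278 to 0.434), Bdnf at 8.29 (0.648 to 1.9) and Msmo1 at 37.8 (24.8 to 26.8). NFD replicate 2 was high in Tspo at 10.7 CPM (3.2 to 3.78), Fosb at 112 (28.1 to 40), Cd36 at 2.19 (0.608 to 0.759), H19 at 14.9 (0.228 to 1.39) and Kif20a at 13.1 (4.72 to 5.17). VPR replicate 2 was high in Emx2 at 23.2 CPM (18.2 to 18.6), Syne3 at 6.7 (5.07 to 5.25) and H19 at 0.564 (0.105 to 0.166). Also apart were NFD replicate 1 in Utp14b at 111 CPM (98.9 to 100) and, low, Pnn at 120 (131 to 133), WT replicate 3 in Rps28 at 56.1 (43.2 to 44.7) and Syne3 at 3.85 (3.42 to 3.45), WT replicate 2 in Tmem101 at 12.7 (12 to 12.1) and VPR replicate 3 in Stac at 2.46 (1.62 to 1.69).

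The interferon list was lower in the VPR libraries, and WT replicate 4 shared its level. Cortical tissue that merely dilutes all striatal RNA evenly is argued against. It would lower both lists alike, but per library the interferon mean minus the shared medium spiny neuron mean differed by -2.69 between VPR and NFD. The exact permutation p (0.0286, the smallest possible) was computed after the interferon means had been seen to separate, so it adds no independent evidence. Less infected tissue in the VPR punches stays open. Zfp189 counts can speak to infection only if the constructs carry the counted exons, which is not known. Their within-construct correlation with the interferon mean was r = 0.65 (Pearson, exact permutation p = 0.0331). It lay at the 87.2 percentile of 1000 genes of like abundance, whose median r was 0.08 and 95th percentile 0.78. It decides nothing about infection. An effect of the VPR construct stays open too. Of the libraries without VPR 1, WT replicate 4, lay inside the range of the VPR libraries, but the rule for reading this count was set afterwards, so it decides nothing. No virus-free or cocaine-free animals are among the samples, so a weaker response to the vector and its repression by VPR cannot be told apart.

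The glutamatergic list was higher in the VPR libraries, with Slc17a7 at 689 ± 544 CPM with VPR and 163 ± 240 CPM with NFD, Nptx1 at 252 ± 150 and 72.4 ± 69.7, and Tbr1 at 89.5 ± 63.3 and 23.9 ± 32.8. Of the 20 list genes 11 reached 1 CPM even in the library with the lowest list mean, and 1 is also on another list. Cortical tissue in the punches is a candidate source that stays open. The within-construct correlation with shared medium spiny neuron markers (Pearson r = -0.43, exact permutation p = 0.131) does not decide it. In the groups without VPR the glutamatergic mean ran from 1.08 to 4.43 (NFD) and from 1.32 to 5.04 (WT). Slc17a7 ran from 3.89 to 512 CPM with NFD and from 6.75 to 729 CPM with WT. These spreads within groups argue against VPR as the only source, and their cause was not tested. A placement of some punches away from the infected tissue may account for both patterns, which is a hypothesis formed on these data. It was prompted by the opposite directions of the glutamatergic and interferon means within constructs (r = -0.87, exact permutation p = 0.00311), so that value is no test of it. VPR replicate 3 had the lowest interferon mean of all libraries (1.20). Its shared medium spiny neuron mean was nevertheless 8.51, within the range of the NFD libraries (8.20 to 8.56). An effect of the VPR construct on the difference between groups stays open. Inside the range of the VPR libraries lay 2 libraries without VPR, NFD replicate 3 and WT replicate 4, a count whose rule was likewise set afterwards.

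DESeq2 called 587 genes in VPR against NFD and 343 in VPR against WT where edgeR called 0 (3878 and 2874 at an unadjusted p under 0.05). With a t distribution on the residual degrees of freedom in place of the normal distribution, 0 of the 587 and 0 of the 343 calls were left, so the normal approximation is a candidate cause. Chance could not be excluded by the splits of the 8 libraries into 4 and 4: 2 of 35, the real grouping included, gave as many DESeq2 calls in VPR against NFD (highest other split 1464) and 5 of 35 in VPR against WT (highest other split 3544). No biological explanation was tested for the difference between the tools.

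The splits did not exclude chance for the unadjusted counts and the lists either, and the numbers of splits again include the real grouping. As many genes at an unadjusted p under 0.05 came from 3 of 35 splits in VPR against NFD (real count 3878, highest other 4956), 30 of 35 in WT against NFD (362, highest other 4357) and 5 of 35 in VPR against WT (2874, highest other 6313). As many lists were called by camera in 18 of 35 splits (17 lists, highest other 27), 34 of 35 (6, highest other 22) and 9 of 35 (21, highest other 26). For genes called by edgeR the splits decide nothing, since a real count of 0 is reached by all 35 of 35. The highest other counts were 0, 253 and 1985. The split that put WT replicate 4 with VPR replicates 1 to 3 called 1985 genes in edgeR and 3544 in DESeq2. It was picked as the highest of the 35, and differs from the real grouping only by exchanging WT replicate 4 and VPR replicate 4. In this split WT replicate 4 stood with VPR replicates 1 to 3 rather than with its labelled group, and the cause was not tested.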

How the results depend on the processing

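Chosen after seeing the data were the settings without the 4 libraries highest in glutamatergic markers, with the glutamatergic mean as a covariate, and with 1 or 2 surrogate variables. As these covariates partly follow the construct, values that shrank or turned with them cannot separate an effect of VPR from differences between mice.

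The count of genes called was 0 in each comparison under RLE scaling, limma-voom, both filters, the 2 groups alone, the replicate block, protein-coding and long non-coding genes only, the threshold of 0.1 and the settings chosen after seeing the data. DESeq2 called 587 genes in VPR against NFD, 343 in VPR against WT and 0 in WT against NFD. Leaving out 1 library gave 0 calls in VPR against NFD and WT against NFD, and 0 to 581 in VPR against WT, the 581 without WT replicate 4. The alternatives kept the direction and side of the threshold for 1615 values of named genes, 59 passed with DESeq2 alone and 34 turned. With 1 library left out 1685 stayed, 26 passed (without WT replicate 4) and 11 turned.

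Lists called fell to 0, 0 and 0 in VPR against NFD, WT against NFD and VPR against WT with an estimated correlation and to 0, 0 and 0 with fry. With the glutamatergic covariate 9 lists were called in VPR against NFD, some of them not called without it, and 9 in VPR against WT. With 1 surrogate variable 7 and 2 lists were called in these comparisons, and with 2 surrogate variables 11 and 7, and 10 in WT against NFD. These counts can also include lists that were not called before or that turned. Leaving out 1 library gave 13 to 24, 5 to 17 and 19 to 28 lists. The call of imprinted genes in VPR against WT (-0.17) ended with the replicate block, a setting for numbers that do not pair the mice: correlations of libraries with the same number ran from -0.54 to 0.39. Over all called lists 162 values kept direction and call, 151 lost the call and 39 turned, and with 1 library left out 490, 33 and 5. The interferon median in VPR against NFD, -3.36 with all libraries, was -3.55 without the 4 libraries, -1.33 with the glutamatergic covariate, and -0.55 and -0.56 with 1 and 2 surrogate variables. In VPR against WT it moved from -2.86 to -3.58, -1.05, -0.31 and -0.19 in the same order. The list was called in each of these, but most of its size was lost with the covariates. The 4 libraries left out include NFD replicate 3 and WT replicate 4, the lowest of their groups in the interferon mean (3.16 and 1.56). A kept gap without them is therefore no independent check. The glutamatergic list moved from 2.51 to -0.07 and from 1.90 to 0.03 with its own mean as covariate, which the model fixes.

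With 1 surrogate variable, the direction turned in VPR against NFD for activated microglia 0, reactive astrocytes 0.24, glutamatergic -0.36, immediate early genes -0.09, presynaptic -0.11, channels -0.09, cholesterol synthesis -0.04, Cnr1 -0.16, Bdnf -0.48, Rims1 -0.03, Kcnj9 -0.08, Zfp189 0.12, Fos -0.07, and in VPR against WT for endothelial 0.03, glutamatergic -0.43, cocaine-linked plasticity 0, presynaptic -0.07, channels -0.01, cell cycle 0.13, oxidative phosphorylation -0.04, cholesterol synthesis -0.04, protocadherin gamma 0.03, H19 0.07, Lmo3 -0.04, Ube2c 0.3, Pdyn 0.04, Penk 0.25, Drd2 0.25, Drd1 0.24. With 2 surrogate variables, the direction turned in VPR against NFD for activated microglia 0, reactive astrocytes 0.24, glutamatergic -0.34, immediate early genes -0.08, presynaptic -0.11, channels -0.09, cholesterol synthesis -0.04, Cnr1 -0.18, Bdnf -0.53, Rims1 -0.03, Kcnj9 -0.1, Zfp189 0.11, Fos -0.03, and in VPR against WT for activated microglia 0.04, reactive astrocytes 0.08, endothelial 0, glutamatergic -0.38, cocaine-linked plasticity -0.03, presynaptic -0.06, channels -0.02, cell cycle 0.26, oxidative phosphorylation -0.04, cholesterol synthesis -0.01, protocadherin gamma -0.01 (the direction of the test), Lmo3 -0.01, Ube2c 0.42, Kif20a 0.05, Zfp189 0.07. Without the 4 libraries highest in glutamatergic markers, the direction turned in VPR against NFD for shared medium spiny neurons 0.02, Drd2 0.1, Fos -0.55, and in VPR against WT for Tac1 0.1, Drd2 0.22, Drd1 0.06, Fos -0.07. With the glutamatergic covariate, the direction turned in VPR against NFD for immediate early genes -0.1, presynaptic -0.04, channels -0.03, Zfp189 0.01, Fos -0.21, and in VPR against WT for oxidative phosphorylation -0.02, Penk 0.02, Drd2 0.09, Drd1 0.07. Called in the turned direction were presynaptic genes (VPR against NFD, 1 and 2 surrogate variables), and with 2 surrogate variables reactive astrocytes (VPR against NFD) and cell cycle genes (VPR against WT). With limma-voom, Fosb turned in VPR against NFD (0.06) and Fos in WT against NFD (0.03). The correlation of the fold changes of VPR and WT against NFD moved from 0.396 to a median of 0.139 with the NFD libraries split between them. The comparisons then share no control, but each also has fewer NFD libraries, and the assignments ran from -0.439 to 0.489. The cause of this and of the other changes was not tested.

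With 1 library left out, the medians in WT against NFD ran from -1.06 to 0.44 for the interferon list, -0.29 to 0 for immediate early genes and -0.11 to 0.02 for ribosomal proteins. Log2 fold changes in VPR against NFD ran from -0.33 to 0 for Zfp189, -0.51 to 0.36 for Fosb and -0.18 to 0.63 for Fos. In WT against NFD they ran from -0.02 to 0.29, -0.77 to 0.09 and -0.52 to 0.29 for the same genes, and in VPR against WT from -0.54 to 0.13 for Drd2 and -0.54 to 0.01 for Drd1. Depth limits genes near the floor of 0.158 to 0.248 CPM, such as Cxcl9 and Plac8 with VPR.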

Other observations

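The genes that follow the interferon and glutamatergic means across libraries were listed only after the correlation of these means had been seen, as were the values of the glutamatergic genes per group.

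With the construct and both list means in 1 edgeR model, 107 of 21276 genes outside the 2 lists were higher with the interferon list mean and 0 lower (adjusted p under 0.05 over these genes). Members of the 2 lists were left out of this count, since they enter the means. Those with the smallest p were Rnf213 (slope 0.92 log2 units per unit, SE 0.05, adjusted p = 9.09e-06), Dtx3l (0.90, SE 0.07), Uba7 (0.87, SE 0.07) and Parp9 (0.94, SE 0.07). Tap1 (1.63, SE 0.14), Slfn8 (1.13, SE 0.1), Trim30d (1.19, SE 0.11) and the immune checkpoint ligand gene Cd274 (1.40, SE 0.13) followed, so these genes varied between mice of 1 group. Exons on the opposite strand share 9.4% of the exon bases of Parp9 and 8.0% of those of Dtx3l, each with the other, and 8.7% of those of Rnf213. The interferon mean went up with the antigen presentation mean (r = 0.99, exact permutation p = 0.000434, adjusted p = 0.00887 over 46 lists; rho = 0.97, exact permutation p = 0.000289, adjusted p = 0.00666; r = 0.97 without the 2 farthest libraries).

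With the glutamatergic mean in the same model, 57 of these genes were higher and 2 lower. The higher genes with the smallest p were Ccn3 (slope 1.22, SE 0.07, adjusted p = 8.41e-06), Sel1l3 (0.75, SE 0.05), the neuropeptide gene Cck (1.45, SE 0.11), Nr4a2 (1.30, SE 0.1), Rtn4rl2 (1.75, SE 0.15) and Scube1 (1.28, SE 0.12). The lower genes were the imprinted gene Peg10 (-0.84, SE 0.09, adjusted p = 0.00223) and Col6a4 (-0.91, SE 0.14, adjusted p = 0.0262). The list genes Slc17a7 and Neurod2 were 230 ± 342 and 24.7 ± 37.3 CPM in WT, with SD values above the means.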
